A study of Cinachyrella cavernosa with 3 samples.

How the data were processed

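Total RNA of the marine demosponge Cinachyrella cf. cavernosa was profiled in 3 libraries, 1 taken before a wound was cut, 1 during regeneration and 1 after regeneration. The wounds imitated bites of fish, per the labels' protocols, and the library taken before the wound served as the control. RNA was isolated with TRIzol, a phenol-based reagent, and libraries were made with Illumina's TruSeq stranded mRNA kit for paired-end sequencing, per the labels' protocols. The hours or days at which the tissue was taken, and how many animals went into each library, are not given in the sources used here.

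The authors deposited 1 table per library, each with an identifier, a read count, a length and an FPKM value for every coding sequence (CDS) listed, per the file headers. FastQC, Trimmomatic and RSEM (a program that estimates transcript abundance and divides reads that map to several sequences among them) are named without versions in the submitters' processing notes. The assembler, the aligner and the rule by which a coding sequence entered a table are not given in the sources used here. Identifiers have the form CDS number and Unigene number, with CDS numbers up to 65526. The files do not pair the identifiers with gene names, and no genome, annotation or sequence was used here, so no coding sequence could be given a function or a position. All 30 gene lists fixed before the data were examined (collagen and matrix, cell adhesion, Wnt, heat shock, ribosomal proteins, stem cell, choanocyte and the others, including the photosynthesis and bacterial lists for foreign RNA) matched 0 identifiers, and none of them could be tested.

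The deposited read counts are whole numbers, and every value in all 3 tables is even, so each read pair appears to have been counted as 2 reads; intervals were therefore computed on pairs. Of 1039 coding sequences with at least 100 reads in a library, 166 fell into 70 sets whose members had the same length and identical counts in every library, the largest with 7 members. One reading, which the sources do not settle, is that a read matching several assembled sequences was counted once for each of them, in which case the total count exceeds the number of reads. The deposited FPKM values (fragment counts scaled by length and library size, by the authors) appear to divide such reads: within these tables FPKM kept at least 90% of the read pairs for 69.9%, 72.5% and 70.4% of coding sequences before the wound, during and after regeneration, and 41, 18 and 29 coding sequences with reads in these libraries had an FPKM of 0. A line was fitted by quantile regression at 0.2 of pairs over FPKM against length. It used all coding sequences with an FPKM above 0, at least 400 bases and 50 pairs. Coding sequences that keep all their reads were assumed, and not shown, to lie near this line. The line gave an estimate of the number of fragments behind the FPKM values as 359267 before the wound, 486180 during and 436332 after regeneration. The fragments held by listed coding sequences were estimated apart from that line, from the 0.2 quantile of pairs over FPKM within short bins of length. They came to 87.7%, 92.4% and 90.8% of the totals. The shares of read pairs kept rest on the same bins and are approximate. For CDS_10096_Unigene_15510 the share before the wound was 2.376, which is more than all of its pairs. Before-wound values of 887 coding sequences were also simulated on such a line, without added noise and with a total of 400000. The line returned 400000, and the bins recovered 98.7% of the assigned fragments. This checks the arithmetic and not how well the line suits the real FPKM values. A coding sequence missing from a table was not read as having 0 reads.

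Counts were scaled by library total times a TMM factor (edgeR 4.0.16 in R 4.3.3, over the 887 coding sequences listed in all 3 libraries, before-wound library as reference), which was 1.206 before the wound, 0.755 during and 1.097 after regeneration, and are given as counts per 1000000 (CPM). Fold changes are on the log2(CPM + 1) scale, which understates the change of low coding sequences, for those listed in both libraries with at least 20 reads in one of them. With 1 library per group there is no spread between samples: no test between conditions was run, and no p-value is given. Differences of at least 4-fold were counted, and named ratios carry an exact conditional binomial 95% interval on read pairs, which covers counting error only and says nothing of animal-to-animal variation. Shares of a library carry an exact binomial (Clopper-Pearson) 95% interval of the same kind. Over all coding sequences compared, the median interval spanned the ratio by a factor of 1.54 to 1.58 to either side. The 4-fold count was tried on simulated counts for 887 coding sequences with 200 changed, in the comparison during against before. It took 98.5% of 8-fold changes and 9.1% of 3-fold changes, and 0.0% and 0.15% of the unchanged ones beside each. Apart from these changes the simulated libraries differed by counting noise alone. The rates therefore leave out variation between libraries and are not error rates of the real counts.

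Named coding sequences are the 2 highest and 2 lowest fold changes of each comparison, the number set for files without gene names, and the most abundant ones of the libraries; this rule, the groups and the comparisons were fixed before the data were examined. The alternatives set beforehand were library totals, median-of-ratios factors, other filters, pseudocounts of 0.1 and 5 and thresholds of 2-fold and 8-fold. FPKM values, sets of identical counts, coding sequences whose FPKM keeps at least 90% of the pairs, leaving out the most abundant coding sequences and reading unlisted ones as 0 were added after seeing the data. Python 3.11.15 with pandas 2.3.3, SciPy 1.17.1 and statsmodels 0.14.6 was used.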

Results

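Messenger RNA of a demosponge was sequenced at 3 stages of wound healing: before the wound, during regeneration and after regeneration, with 1 library per stage. The tables listed 1928 coding sequences with 773142 reads before the wound, 1769 with 1062098 reads during regeneration and 2127 with 965464 reads after regeneration. The median coding sequence had 52, 48 and 48 reads in these libraries. Lengths ran from 258 to 5346 bases with a median of 399, and all were multiples of 3. Because each stage had 1 library, every difference below compares these libraries, and its interval covers counting error only.

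The stages differed in which coding sequences were listed at all. Of 3229 coding sequences listed in any library, 887 were listed in all 3, and these held 86.55%, 94.7% and 90.02% of the reads before, during and after regeneration. Another 532 were listed before the wound only, 494 during regeneration only and 495 after regeneration only. The before and after libraries shared 433 that were not listed during regeneration, and the during and after libraries shared 312 that were not listed before the wound. Before and during shared 76 that were not listed afterwards. Most of the sequences listed in a single library were low, with medians of 30, 30 and 26 reads. Abundant ones went unlisted as well: of the 419 coding sequences with at least 200 reads before the wound, 95 (22.7%) were not listed during regeneration and 30 (7.2%) were not listed after it. Of the 355 with at least 200 reads during regeneration, 59 (16.6%) were not listed before the wound. Copies with identical counts enter these numbers separately. Among the 95 are 4 sequences with the same 1116 reads before the wound.

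**Figure D1:**
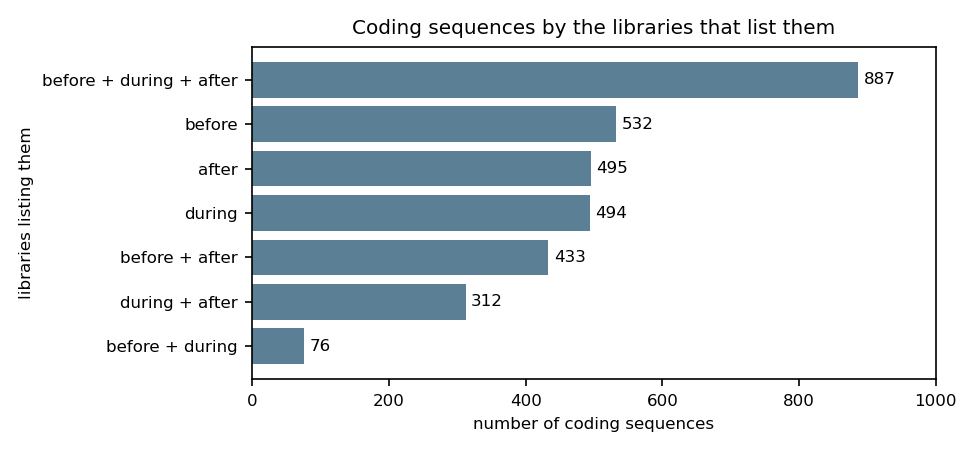
Number of coding sequences (horizontal axis) by the combination of libraries that list them (vertical axis). The 887 listed in all 3 libraries form the longest bar, and the 76 listed before the wound and during regeneration but not afterwards the shortest.

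A small group of highly abundant coding sequences took a larger part of the reads during regeneration. The 10 most abundant held 44.1% of reads before the wound (95% interval 43.952 to 44.265), 68.5% during regeneration (68.407 to 68.657) and 52.4% after it (52.246 to 52.528). The 3 sets of 10 comprised 13 coding sequences, 8 of them common to all 3 libraries. By read count CDS_6383_Unigene_9864 (375 bases) ranked first before the wound, at 7.34% of reads, and after regeneration, at 9.64%. By FPKM, which kept 63% and 56% of its read pairs, CDS_56343_Unigene_88040 ranked first before the wound and CDS_6894_Unigene_10670 after regeneration. CDS_41997_Unigene_65739 (300 bases) ranked first during regeneration by both. It took 3.26% of reads before the wound (3.207 to 3.319), 19.2% during regeneration (19.137 to 19.349) and 4.66% after it (4.6 to 4.719). Its CPM was 9.42-fold higher during regeneration than before, and 6.0-fold lower after regeneration than during it. These folds depended on the scaling: on the log2 scale they were 3.24 and -2.58, against 2.56 and -2.05 with library totals and 2.42 and -1.93 with deposited FPKM. CDS_50279_Unigene_78645 (837 bases) had 18214 reads before the wound and 15904 after regeneration and was not listed during regeneration, where 15669 reads would have been expected at the before-wound level. Of the 12 abundant coding sequences listed both before and during, 6 were at least 2-fold higher during regeneration and 0 were at least 2-fold lower. Scaled by library totals instead, 3 were at least 2-fold higher and 2 at least 2-fold lower, and the direction of 4 of the 12 reversed. After regeneration, 12 of the 13 lay within 2-fold of the before-wound level and 1 was above it.

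**Figure D2:**
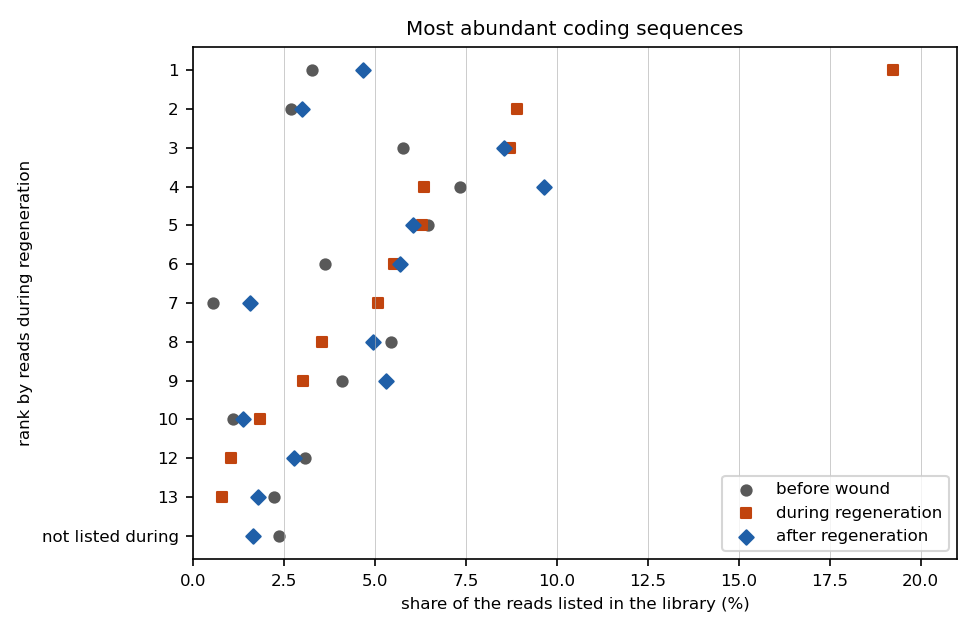
Share of the listed reads in percent (horizontal axis) of the 13 coding sequences among the 10 most abundant of any library, ordered by rank during regeneration (vertical axis), with 1 symbol per library. The first-ranked sequence stands at 19.2% during regeneration against 3.26% before the wound and 4.66% after regeneration.

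The first comparison asked which coding sequences differed between regenerating tissue and tissue before the wound. During regeneration 89 of 908 coding sequences were at least 4-fold higher and 85 at least 4-fold lower, while 456 (50.2%) lay within 2-fold. The highest fold belonged to CDS_61609_Unigene_96275 (297 bases), with 18 reads before the wound, 2172 during and 738 after regeneration. Its log2 fold change during regeneration was 7.06 (95% interval 6.2 to 8.26), a 133-fold difference. CDS_715_Unigene_1122 (297 bases) had 16 reads before the wound, 492 during and 8 after regeneration, a log2 fold change of 5.08 (4.16 to 6.39) during regeneration. The lowest fold belonged to CDS_43612_Unigene_68238 (378 bases), with 576 reads before the wound, 14 during and 274 after regeneration, at a log2 fold change of -5.07 (-6.47 to -4.08). CDS_28208_Unigene_43952 (372 bases) had 486, 28 and 510 reads, at a log2 fold change of -3.86 (-4.79 to -3.13) during regeneration. FPKM kept 98% or more of the read pairs of these 4 coding sequences, so there was no sign that their reads were shared with a copy. The counting intervals of all 89 higher and 85 lower differences of at least 4-fold excluded equal levels. The filter on reads and the 4-fold threshold largely fix this outcome, so it is no further evidence for these differences. The balance of higher and lower calls depended on the scaling: with library totals, which moved the median of all coding sequences to -0.69 on the log2 scale, 28 were higher and 157 lower. Coding sequences listed in only 1 of the 2 libraries do not enter these counts, here or in the next 2 comparisons; with unlisted ones read as 0 reads, 620 were higher and 788 lower.

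**Figure D3:**
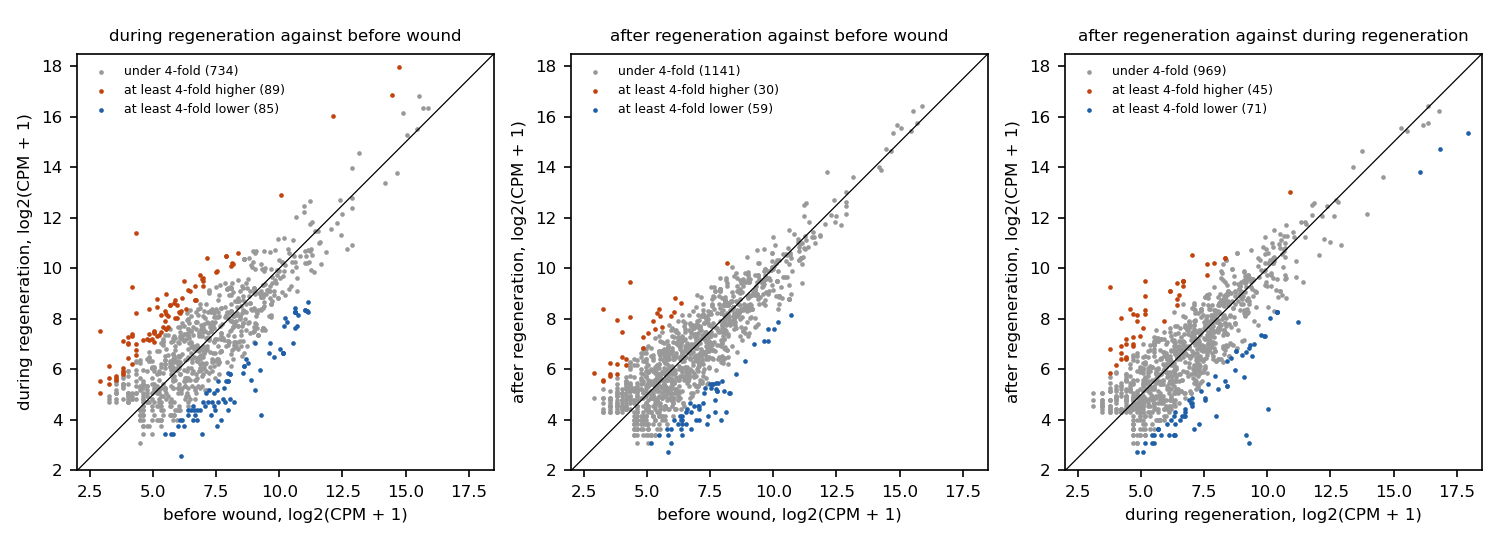
Abundance as log2(CPM + 1) of each coding sequence listed in both libraries of a comparison, with at least 20 reads in one of them; points are coding sequences and the line marks equality. Those at least 4-fold apart number 89 higher and 85 lower during against before, 30 and 59 after against before, and 45 and 71 after against during.

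The second comparison asked how far tissue after regeneration differed from tissue before the wound. Fewer coding sequences were far apart here: 30 of 1230 were at least 4-fold higher after regeneration, 59 were at least 4-fold lower, and 824 (67.0%) lay within 2-fold. With unlisted sequences read as 0 reads the balance turned, to 543 higher and 479 lower. CDS_49760_Unigene_77850 (357 bases) had 8 reads before the wound, 18 during and 350 after regeneration, at a log2 fold change of 5.11 (95% interval 3.89 to 7.16) after against before. CDS_61609_Unigene_96275, the sequence with the highest fold during regeneration, was still higher, at 5.10 (4.23 to 6.31). CDS_16596_Unigene_25728 (306 bases) had 228 reads before the wound and 16 after regeneration, at -3.93 (-5.26 to -2.99). CDS_29575_Unigene_46143 (921 bases) had 258 and 20 reads, at -3.80 (-4.97 to -2.95). The latter pair was not listed during regeneration. The difference in the number of calls between this comparison and the first was not tested, since neither has replicates.

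The third comparison set tissue after regeneration against tissue during it. After regeneration 45 of 1085 coding sequences were at least 4-fold higher, 71 were at least 4-fold lower and 678 (62.5%) lay within 2-fold. CDS_40420_Unigene_63274 (375 bases) had 170 reads before the wound, 10 during and 640 after regeneration, at a log2 fold change of 5.49 (95% interval 4.36 to 7.23) after against during. CDS_60028_Unigene_93815 (576 bases) had 28 reads during and 764 after regeneration, at 4.33 (3.6 to 5.25), and was not listed before the wound. CDS_715_Unigene_1122, high during regeneration, was lower afterwards by the widest margin, at -6.17 (-8.23 to -4.97). CDS_1053_Unigene_1630 (384 bases) had 76 reads before the wound, 458 during and 10 after regeneration, at -5.78 (-7.55 to -4.67). With library totals, which moved the median to 0.50, the split turned to 85 higher and 24 lower, and with unlisted sequences read as 0 reads it turned to 687 and 452.

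Across the 869 coding sequences listed in all 3 libraries with at least 20 reads in one, log2 abundance was most alike between the libraries before the wound and after regeneration, with a Pearson r of 0.884 and a Spearman rho of 0.854. The after and during libraries gave 0.839 and 0.8, and the during and before libraries 0.765 and 0.707. These are correlations across coding sequences, which are not independent replicates. The coding sequences at least 4-fold higher during regeneration had a median log2 difference from the before-wound library of 2.5 during and 1.1 after regeneration, and those at least 4-fold lower had -2.48 and -0.96. Of the 86 higher ones, 38 (44.2%) were within 2-fold of the before-wound level after regeneration and 12 (14.0%) were still at least 4-fold above it. Of the 79 lower ones, 39 (49.4%) were within 2-fold and 14 (17.7%) still at least 4-fold lower. The share within 2-fold depended on the threshold: it was 62.5% and 64.8% for sequences at least 2-fold higher and lower, and 22.2% and 50% for those at least 8-fold. Both comparisons share the before-wound library, and sequences picked for being far apart tend to lie closer in another library. In 100 simulations with no stage effect and a log2 noise SD of 0.9 per library, 32.9% (range 15.9 to 52.1) of the higher and 41.3% (25.4 to 53.1) of the lower ones came within 2-fold, but that SD was taken from the observed differences between stages and set equal in the 3 libraries, so any stage effect counts as noise in it and these simulations do not decide whether the return was more than expected. The 12 higher and 14 lower calls common to both comparisons compare with 2.2 and 2.6 for independent lists, a reference that leaves out the shared library. The same simulations, which include it, kept 33.3% and 24.8% of the calls, against the 14.0% and 17.7% observed, with the same limit. Among the 869, 22 were at least 4-fold higher and 29 at least 4-fold lower after regeneration than before. The 22 are too few to make up 33.3% of the 86, a share simulated with equal noise. The simulated shares therefore set no expectation for the overlap. Of the 22 and 29, 12 (54.5%) and 14 (48.3%) were also called during regeneration, and 4 (18.2%) and 6 (20.7%) then lay within 2-fold of the before-wound level. Part of the overlap may come from the shared control, which is 1 library and could not be split.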

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

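The tests below on the listing of coding sequences were chosen after the listing had been seen; the predictions for adjacent numbers and for the listing rule preceded their values, and that for depth did not. Coding sequences listed after wounding but not in the before-wound control lie outside the fold comparisons with that control, and each group was led by sequences far above 6 reads, the smallest count listed in the control. During regeneration only, 494 coding sequences were listed, led by CDS_9704_Unigene_14925 (651 bases) with 1384 reads. After regeneration only, 495 were listed, led by CDS_25014_Unigene_38835 (2286 bases) with 518 reads. Another 312 were listed during and after regeneration, led by CDS_13032_Unigene_20138 (870 bases) with 840 reads during and 22 after.

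The reverse case, abundant coding sequences of the control that were not listed during regeneration, was weighed. The effective library size during regeneration was 0.86 of that before the wound (0.89 with median-of-ratios factors and 1.37 with library totals). A ratio under 0.02 would be needed to bring 200 reads below 4, the smallest count listed during regeneration. This argues against lower depth only if sequences with at least 4 reads were listed, and the rule of listing is unknown. Of the before-wound sequences under 50 reads, 67.0% went unlisted during regeneration, against 22.7% of those with at least 200. The bound of 0.02 was set when the ratio was already known, and with these library sizes it was out of reach. This test replaced an earlier one on the reads expected of the 95 such sequences, which was dropped because the choice of sequences with at least 200 reads fixed its outcome. For reads moved to a sequence with an adjacent Unigene number, at least 50% of the 95 sequences were required to have such a neighbour listed during regeneration. Of the 95, 4 (4.2%, 95% interval 1.2 to 10.4) had one, and the rest had no listed adjacent sequence to take their reads. Adjacent numbers were sparse, with 252 such pairs among 3229 coding sequences. The 50% could hardly be reached, so the outcome of this test says nothing of reads moved elsewhere. This test took the place of one on all adjacent pairs, dropped because most of those pairs lie outside the 95. Copies with distant numbers, or unlisted ones, were not examined. The rule by which sequences were listed stays open. At their before-wound level the 95 sequences would take 19662 fragments, and all 965 before-wound sequences unlisted during regeneration would take 33092. The FPKM values leave 36953 fragments outside the list during regeneration, so the 95 sequences could be expressed and unlisted. That remainder rests on separate estimates of the total and of the listed part, so it is approximate, and the margin for all 965 is small. In the simulated before-wound values the bins recovered 98.7% of the assigned fragments. A shortfall of that size in the 449227 fragments of the listed part during regeneration would exceed the margin. For all 965 the values therefore decide nothing. A difference between stages, or between the animals sampled, is also open and was not tested.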

How the results depend on the processing

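With 1 library per stage no setting tests a difference, no library can be left out within a stage, and the depth of 359267 to 486180 fragments limits what low coding sequences can show. Values planned for the gene lists could not be given because no identifier matched, and no paired analysis was possible. The counts of sequences at least 4-fold apart are given as higher and lower, in the order during against before, after against before, and after against during. They were 89 and 85, 30 and 59, and 45 and 71. A threshold of 2-fold gave 240 and 212, 182 and 224, and 172 and 235, and one of 8-fold gave 18 and 21, 5 and 10, and 12 and 10, as the thresholds themselves require. Library totals gave 28 and 157 for the first comparison and 85 and 24 for the third, and the deposited FPKM values gave 29 and 183, and 117 and 25; both settings shift the median of all coding sequences (by -0.69 and -0.73 in the first comparison), while FPKM centred on its median stayed within 1.5 times of each count. After that centring 74 of 83 higher and 78 of 84 lower calls of the first comparison remained, with 0 changing sign. A filter of 100 reads, which leaves fewer sequences to compare, gave 19 and 37 in the second comparison and 44 lower in the third. Sequences whose FPKM keeps at least 90% of the pairs gave 50 lower in the first comparison, again over fewer sequences. Reading unlisted sequences as 0 reads gave 620 and 788, 543 and 479, and 687 and 452, which adds the sequences listed on one side. Median-of-ratios factors, no filter, pseudocounts of 0.1 and 5, 1 sequence per set of identical counts and leaving out the most abundant sequences stayed within 1.5 times of every count. The 10 most abundant held 44.1%, 68.5% and 52.4% of reads before, during and after; the 50 most abundant held 63.7%, 80.2% and 70.2%, and with pairs as assigned by FPKM the 10 held 48.1%, 69.5% and 54.2%. The share within 2-fold of the before level after regeneration was 62.5% (higher) and 64.8% (lower) at a 2-fold threshold. At 4-fold it was 44.2% and 49.4%, and at 8-fold 22.2% (higher, 18 sequences) and 50% (lower, 20 sequences). Why both shares fell from 2-fold to 4-fold was not tested. The 144 alternative values of the 2 highest and 2 lowest folds of each comparison kept direction and stayed inside their counting interval. Settings that only select sequences could not move these folds, and folds this extreme could hardly reverse. CDS_41997_Unigene_65739, added after its folds had been seen, kept its direction in all 3 comparisons but left its narrow counting interval with library totals and both forms of FPKM, and in the first and second also with median-of-ratios factors; its log2 fold during against before was 3.24, and 2.56 with library totals. Library totals reversed the direction of 4 of 12, 1 of 13 and 2 of 12 of the most abundant sequences in the 3 comparisons. The 9 alternative correlations moved by less than their interval across coding sequences.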

Other observations

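The tests of the first pattern here were chosen after it had been seen; the prediction for the second preceded its value. Among the 869 coding sequences compared in all 3 libraries, the level after regeneration lay between the other 2 levels for 445 (51.2%), against 220 (25.3%) for the before-wound level and 204 (23.5%) for the level during regeneration. A random order gives 33.3%, and 100 simulations with equal noise in each library gave 29.6 to 37.4% for the after-regeneration library. Equal noise puts the simulated share near 33.3% by symmetry. The simulations therefore do not show what libraries with unequal noise would give. The variance particular to each library, from the 3 pairwise differences, was 0.18 on the squared log2 scale after regeneration, 0.94 before the wound and 1.32 during regeneration. In the listing, 76 coding sequences were shared by the before and during libraries and missing afterwards, against 433 and 312 for the other pairs, but the after-regeneration library did not have fewer sequences of its own (495) than the during library (494), and the before-wound library had 532. Counting noise is argued against as the cause: among the 85 coding sequences with at least 500 reads in every library the after-regeneration level was the middle one in 57.6% (95% interval 46.4 to 68.3). A mix of RNA or reads from the other 2 libraries stays open: 19.1% of 887 coding sequences (169; 16.5 to 21.8) lay above or below both beyond the counting interval, 56 of them by at least 2-fold, but noise between preparations is unmeasured with 1 library per stage, so this does not decide it. Another candidate explanation is a state after regeneration partway between the regenerating and the unwounded tissue; a difference between animals would be as compatible with 1 library per stage, and neither was tested.

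Whether the concentration of reads in a few coding sequences during regeneration sets the balance of calls under library totals stays open. With library totals 84.9% of the 185 coding sequences at least 4-fold apart during against before were lower. With the 13 most abundant coding sequences left out, that share was 42.7% of 178. The value came where the prediction put it, but leaving sequences out of the totals moves every other fold by one common amount, so it does not decide the question. Whether their larger share reflects the stage, the animal or the library preparation was not tested, and no gene name is at hand to say what they encode.

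Sequences with adjacent numbers tended to be listed in the same libraries: 120 of 252 adjacent pairs had identical listings, against 28 to 66 in 1000 shuffles, and 88 of the 220 pairs whose counts were not identical, against 21 to 59. Pairs with identical counts have identical listings by construction. The other 220 pairs can still hold near-copies that share reads. For example, CDS_13552_Unigene_20956 and CDS_13553_Unigene_20957 had 104 and 120 reads before the wound, where the former had an FPKM of 0. The 88 of 220 therefore do not show that distinct neighbours were listed together. The run of 4 sequences from CDS_6425_Unigene_9925 on has identical counts. Each is 429 bases long with 1116 reads before the wound and 512 after regeneration, and none was listed during it.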
